A study of Streptococcus mutans with 18 samples.

How the data were processed

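Streptococcus mutans UA159, a laboratory strain of a species that lives in dental plaque, was profiled by RNA sequencing in 18 libraries. Per the labels, cells grew to mid-exponential phase in the medium FMC, either plain or with arginine added to 1.5%, and the condition was pH 7.0, pH 5.5 or 0.5 mM hydrogen peroxide. This gave 6 groups of 3 libraries. Per the labels' protocols, ribosomal RNA was depleted with a bacterial mRNA enrichment kit and single-end reads were made from libraries of a directional kit. The labels number the repeats of each group and do not say whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

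The deposited files hold whole-number read counts per locus made by the authors, in 4 count columns and their sum for each library. The submitters' processing notes name cutadapt, Bowtie, HTSeq and edgeR. Their versions, the genome build and the counting mode, strand included, are not given in the sources used here, so reads of overlapping or antisense loci could not be separated from one another. In every row the sum column equalled the 4 count columns, and it was used as the count. In FMC_arginine_pH5.5 replicate 3 the second and the fourth column were identical, so its total of 6950012 counts holds 1 column counted again. Without that repeat it came to 5215112 counts. The 12 libraries outside pH 5.5 hold 2042 loci each, 15 of them rRNA and 65 tRNA. The 6 libraries at pH 5.5 hold 1962 loci and no rRNA or tRNA rows, so their counts were made or filtered differently. That difference cannot be told apart from pH in any comparison of pH 5.5 with pH 7. The effects of arginine were each computed within 1 condition and therefore within 1 such batch.

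Library sizes and tests used the 1962 other loci, and every count carried a locus tag. Their totals ranged from 2472796 to 19195007 counts per library. The coefficient of biological variation estimated over all 6 groups was 22.2%, and within single groups it ran from 14.8% in FMC_H2O2 to 37.4% in FMC_arginine_pH5.5. Counting error is small beside this spread for most loci. Bounds for loci at 0 were set at 3 counts over the group's total and cover counting error only.

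Loci were tested in R 4.3.3 with edgeR 4.0.16. Low loci were removed with filterByExpr at its defaults, which left 1933, and libraries were scaled by TMM. One quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) had 1 coefficient for each of the 6 groups over all 18 libraries. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The standard error of a log2 fold change was its size divided by the square root of F. Unless another test is named, adjusted p-values below come from this model. There were 5 comparisons of 2 groups and 2 tests of the difference between arginine effects. Levels are means of CPM, computed here with the cpm function of edgeR, with SD over 3 libraries.

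The files pair no locus tag with a gene name. The reference table supplied, of assembly ASM1904864v1 of another strain, matched 0 of the 1962 tags, so loci are named by tag. Gene lists were fixed by locus number from general knowledge of the UA159 annotation, before the data were examined, and so were the tests, the alternatives and the rule for named loci. A check of that knowledge used gene order alone. Of 146 recalled symbols, 97 occurred once in the table of the other strain, and 95 of these stood in the same order as the locus numbers, allowing for 1 inverted segment. Product descriptions were not available for dropping a listed locus whose product contradicts its list, so this planned step was not applied, and what a listed locus does is background and not a result.

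Of 28 lists fixed, 27 were built. The list of ribosomal proteins needs symbols and was not analysed here. The lists cover the agmatine deiminase system, arginine biosynthesis, pyrimidine synthesis with carbamoyl phosphate, purine synthesis, branched-chain amino acid synthesis, the glutamine, glutamate and citrate pathway, oligopeptide permease, glucan and fructan enzymes with surface adhesins, ComCDE and bacteriocins, late competence and DNA uptake, the F1Fo ATPase, malolactic fermentation and oxalate, fatty acid synthesis, chaperones and Clp proteases, oxidative stress defence, SUF iron-sulfur cluster assembly, manganese, iron and zinc transport, copper efflux, sugar phosphotransferase systems, the lactose and tagatose pathway, the multiple sugar metabolism operon, glycogen and maltodextrin, pyruvate and fermentation enzymes, two-component systems and cell envelope, Lrg and Cid, and the mobile elements TnSmu1 and TnSmu2. The 26 lists with at least 4 tested members were tested against all other loci with camera (limma 3.58.1) on log2 CPM with a prior count of 2. A list was called at a preset correlation of 0.01 and an adjusted p under 0.05 within its comparison. For calls in the fit on all libraries the p with an estimated correlation is given as well. List calls under other settings are given at the preset correlation alone. The fry test, which asks only whether a list's members move one way on balance, was run as well.

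Named loci followed a rule. For each comparison of 2 groups they were the 10 highest and the 10 lowest log2 fold changes among called loci with a mean log2 CPM of at least 4 and no overlap between the groups, and up to 4 called members of each list. For each difference of effects they were the 5 highest and the 5 lowest. The text prints some of these.

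The model was tested on simulated counts with known changes. For the arginine effect at pH 7, with 1932 loci run, it recovered 68% of loci changed by 1 on the log2 scale, 100% of those changed by 2 and 16.3% of those changed by 0.5, and 4.35% of its calls were false. Over the 5 comparisons of 2 groups the false share ran from 4.32% to 6.59%, the highest for pH 5.5 against pH 7. The simulation gave each locus 1 spread in all 6 groups. It therefore does not test the error where groups differ in spread, as those at pH 5.5 did. It also left most loci unchanged, 1719 of 1932 for pH 5.5 against pH 7. The real comparisons called 79.9% of loci there and 55.5% for arginine at pH 5.5. The false share and the scaling where most loci change were therefore not tested. Alternatives were DESeq2 1.42.0 as a test and as a scaling, upper-quartile scaling, limma-voom, other filters, fits on fewer groups, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were the distinct count columns alone, leaving out loci near 0 at pH 5.5, the 12 libraries outside pH 5.5 alone, and leaving out FMC_arginine_pH5.5 replicate 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.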

Results

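The data comprised read counts for 1962 loci of S. mutans UA159 in 6 groups of 3 libraries, which were FMC medium at pH 7.0 (FMC_pH7), at pH 5.5 (FMC_pH5.5) and with 0.5 mM hydrogen peroxide (FMC_H2O2), and the same conditions with 1.5% arginine (FMC_arginine_pH7, FMC_arginine_pH5.5 and FMC_arginine_H2O2). In replicate order, FMC_pH7 held 4612287, 6175527 and 3504531 counts outside rRNA and tRNA, and FMC_arginine_pH7 held 6403669, 4041579 and 6773147. FMC_pH5.5 held 5017297, 2524594 and 2509975, and FMC_arginine_pH5.5 held 5618507, 2472796 and 6950012. FMC_H2O2 held 8045493, 7937167 and 19195007, and FMC_arginine_H2O2 held 7039724, 11151425 and 15489274. The rRNA share of all counts was 69.5% ± 8.22 (SD, n = 3) in FMC_pH7, 43.2% ± 2.96 (n = 3) in FMC_arginine_pH7, 46.1% ± 0.712 (n = 3) in FMC_H2O2 and 45.4% ± 4.34 (n = 3) in FMC_arginine_H2O2.

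Libraries were placed on an axis from the mean profile of FMC_pH5.5 (0) to that of FMC_pH7 (1). The FMC_arginine_pH7 libraries lay at 0.847, 0.896 and 0.881, and the 6 libraries with hydrogen peroxide lay between 0.859 and 0.923. The FMC_arginine_pH5.5 libraries were spread out, at 0.595, 0.147 and 0.406.

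**Figure D1:**
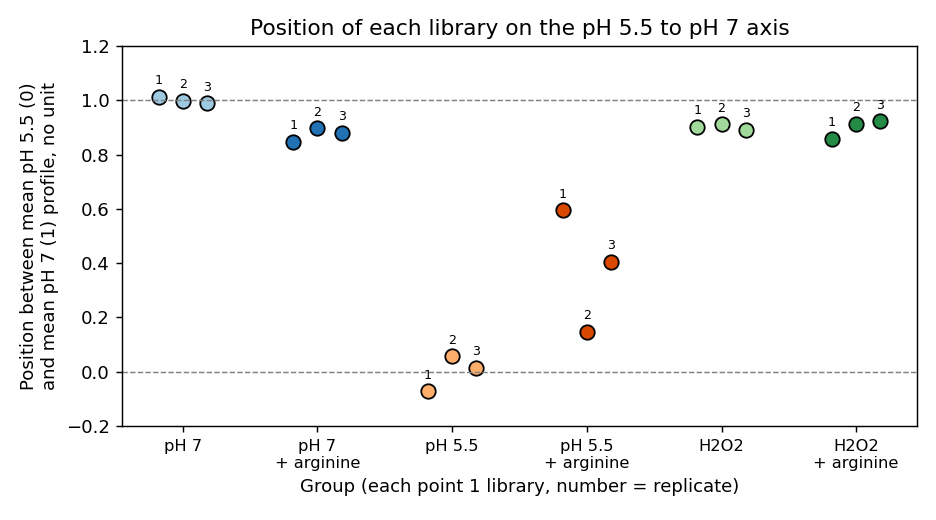
Position of each library (points, numbered by replicate, 3 per group) on the axis from the mean FMC_pH5.5 profile at 0 to the mean FMC_pH7 profile at 1 (vertical axis, no unit), by group (horizontal axis). FMC_arginine_pH5.5 replicate 2, at 0.147, lies nearest to the libraries at pH 5.5 without arginine.

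The first comparison asked how arginine changed transcript levels at pH 7. The loci of TnSmu1, an integrated mobile element, fell together, with 25 of 30 tested members lower and a median log2 fold change of -2.58. SMU_197c went from 175 ± 58.4 to 24.5 ± 1.86 CPM (SD, n = 3 each), a log2 fold change of -2.84 ± 0.23 (SE, edgeR adjusted p = 1.8e-06). The list was lower by camera (adjusted p = 1.03e-26), a call lost with an estimated correlation (adjusted p = 0.12). Members of the glutamine, glutamate and citrate pathway also fell, 4 of 9, among them SMU_670, which went from 250 ± 113 to 80.3 ± 1.18 CPM (log2 -1.64 ± 0.24 SE, edgeR adjusted p = 0.000165, n = 3 each), and SMU_671 (log2 -1.70). That list was lower by camera (adjusted p = 0.000971; adjusted p = 0.324 with an estimated correlation), with 5 members lower when adjusted over the list alone.

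Chaperone and Clp protease loci rose, 6 of 14 (with 1 lower when adjusted over the list alone), led by the neighbouring loci SMU_80 to SMU_83 with log2 fold changes of 1.69, 1.68, 1.64 and 1.58. SMU_82 went from 590 ± 47.5 to 1842 ± 296 CPM (SD, n = 3 each; edgeR adjusted p = 3.29e-05). The list was higher (camera adjusted p = 0.0114; adjusted p = 0.324 with an estimated correlation), but its median was only 0.04 against a mean of 0.52, and the list was not called in the fit on these 2 groups (adjusted p = 0.0739) or on the 12 libraries outside pH 5.5 (adjusted p = 0.0586). The F1Fo ATPase, the proton pump of the membrane, was higher as a list with a median of 0.45 (camera adjusted p = 0.00812; adjusted p = 0.324 with an estimated correlation), with 2 of 8 members called, 4 when adjusted over the list alone and 7 in the fit on these 2 groups. Both F1Fo calls ended without FMC_pH7 replicate 1 or 2 or FMC_arginine_pH7 replicate 1 or 3, and 1 ended without FMC_arginine_pH7 replicate 2. SUF iron-sulfur cluster assembly was lower with a median of -0.36 (camera adjusted p = 0.0218; adjusted p = 0.324 with an estimated correlation), with 1 of 5 members called, a call that ended whichever of the 6 libraries was left out, 3 when adjusted over the list alone and all 5 in the fit on these 2 groups. Without FMC_arginine_pH7 replicate 2 the SUF list was not called (adjusted p = 0.0581).

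Glucan and fructan enzymes with surface adhesins, which serve sticky polymer synthesis and attachment, split into 4 higher and 4 lower of 13 (camera adjusted p = 0.784). SMU_910 rose from 2401 ± 144 to 7718 ± 1002 CPM (log2 1.68 ± 0.20 SE, edgeR adjusted p = 2.37e-05, n = 3 each) and SMU_2028 rose by 1.50 on the log2 scale. SMU_1396 went down to a log2 fold change of -1.53, and SMU_1004 went from 4085 ± 509 to 1524 ± 263 CPM (log2 -1.42 ± 0.20 SE, n = 3 each). SMU_1004 and its neighbour SMU_1005 are similar in sequence as far as is generally known, so how reads from alike stretches were split between them is uncertain. Of the ComCDE and bacteriocin list 4 of 13 fell (5 adjusted over the list alone), of glycogen and maltodextrin 3 of 11 fell (4, with 2 higher, adjusted over the list alone), and of Lrg and Cid 2 of 4 fell, while 3 of 16 TnSmu2 loci rose. The ComCDE members called came to 1 without FMC_pH7 replicate 2 or 3 or any FMC_arginine_pH7 library, and the glycogen members to 1 without any FMC_pH7 library or FMC_arginine_pH7 replicate 3. Of the 2 Lrg and Cid calls, 1 was left without FMC_pH7 replicate 1 or 2, and both ended without FMC_pH7 replicate 3 or any FMC_arginine_pH7 library. Pyruvate and fermentation enzymes had 1 member higher, SMU_148 (log2 1.38), and 4 lower of 9. The 4 lower calls ended without FMC_pH7 replicate 3 or FMC_arginine_pH7 replicate 1 or 3, and 1 was left without FMC_arginine_pH7 replicate 2. Of these 4, SMU_1421 stood at 182.7 ± 272.8 CPM in FMC_pH7 (SD, n = 3), and its log2 fold change of -3.53 came to -0.68 without FMC_pH7 replicate 3. Its edgeR adjusted p was then 0.232, and it was 0.0571, 0.0563 and 0.0548 without FMC_arginine_pH7 replicate 1, 2 or 3. SMU_1117 of oxidative stress defence fell by 1.33 on the log2 scale. Branched-chain amino acid synthesis, manganese, iron and zinc transport, and two-component systems each had 1 member higher, SMU_233, SMU_186 and SMU_1515, and 6, 3 and 4 members higher in the fit on these 2 groups. The calls of SMU_233 (edgeR adjusted p from 0.0688 to 0.111) and SMU_1515 (from 0.066 to 0.0858) ended whichever of the 6 libraries was left out, and that of SMU_186 ended without FMC_pH7 replicate 1 or 3 (adjusted p = 0.0766 and 0.0765) or FMC_arginine_pH7 replicate 1 or 3 (adjusted p = 0.0803 and 0.0615). By the edgeR test no member passed in 12 lists with 111 tested members, of which 17 had an unadjusted p under 0.05 and 4 were called by DESeq2. These were the lists of the agmatine deiminase system, arginine biosynthesis, pyrimidine and purine synthesis, oligopeptide permease, late competence, malolactic fermentation, fatty acid synthesis, copper efflux, sugar phosphotransferase systems, lactose and tagatose, and multiple sugar metabolism. Without FMC_pH7 replicate 3 copper efflux had 1 member called, and without FMC_pH7 replicate 1 the phosphotransferase systems had 1. Adjusted over the list alone, 2 of the 3 copper efflux loci and 2 of the two-component loci were higher.

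The fit on these 2 groups alone called members in 7 of these 12 lists. Purine synthesis had 3 higher, arginine biosynthesis 2 lower, late competence 3 lower, fatty acid synthesis 1 higher and 4 lower, phosphotransferase systems 5 higher and 3 lower, multiple sugar metabolism 2 higher and copper efflux 1 higher. In the 5 others edgeR called 0 of 30 members there, 3 had an unadjusted p under 0.05, and DESeq2 on all libraries called 0. Of the lists with members called in the fit on all libraries, glycogen and maltodextrin had 2 higher and 6 lower in the fit on these 2 groups, oxidative stress defence 2 higher and 1 lower, pyruvate and fermentation enzymes 1 higher and 1 lower, and Lrg and Cid 1 lower. In that fit camera called purine and branched-chain amino acid synthesis higher and late competence lower (adjusted p = 0.0282 each). Without FMC_pH7 replicate 3 it called purine and branched-chain synthesis (adjusted p = 0.0391 and 0.0404). Without FMC_pH7 replicate 1 it called late competence and ComCDE lower and TnSmu2 higher (adjusted p = 0.0175, 0.00625 and 0.0389), and without FMC_arginine_pH7 replicate 1 it called TnSmu2 (adjusted p = 0.000255). ComCDE was also called with at least 50 counts required and with a replicate block (adjusted p = 0.0431 and 0.0289), TnSmu2 with at least 50 counts (adjusted p = 0.0431), and late competence on the 12 libraries (adjusted p = 0.0194).

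Across all 1933 loci tested, 194 were called, 91 higher and 103 lower, and 47 and 65 of these changed at least 2-fold. Outside the lists, SMU_936 and SMU_932 rose by 2.58 and 2.42 on the log2 scale. The count was 500 in a fit on these 2 groups alone and 623 in a fit on the 12 libraries outside pH 5.5. It was 125 without FMC_pH7 replicate 2, and 123, 127 and 122 without FMC_arginine_pH7 replicate 1, 2 or 3. The rRNA share also differed between these groups, as given above.

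**Figure D2:**
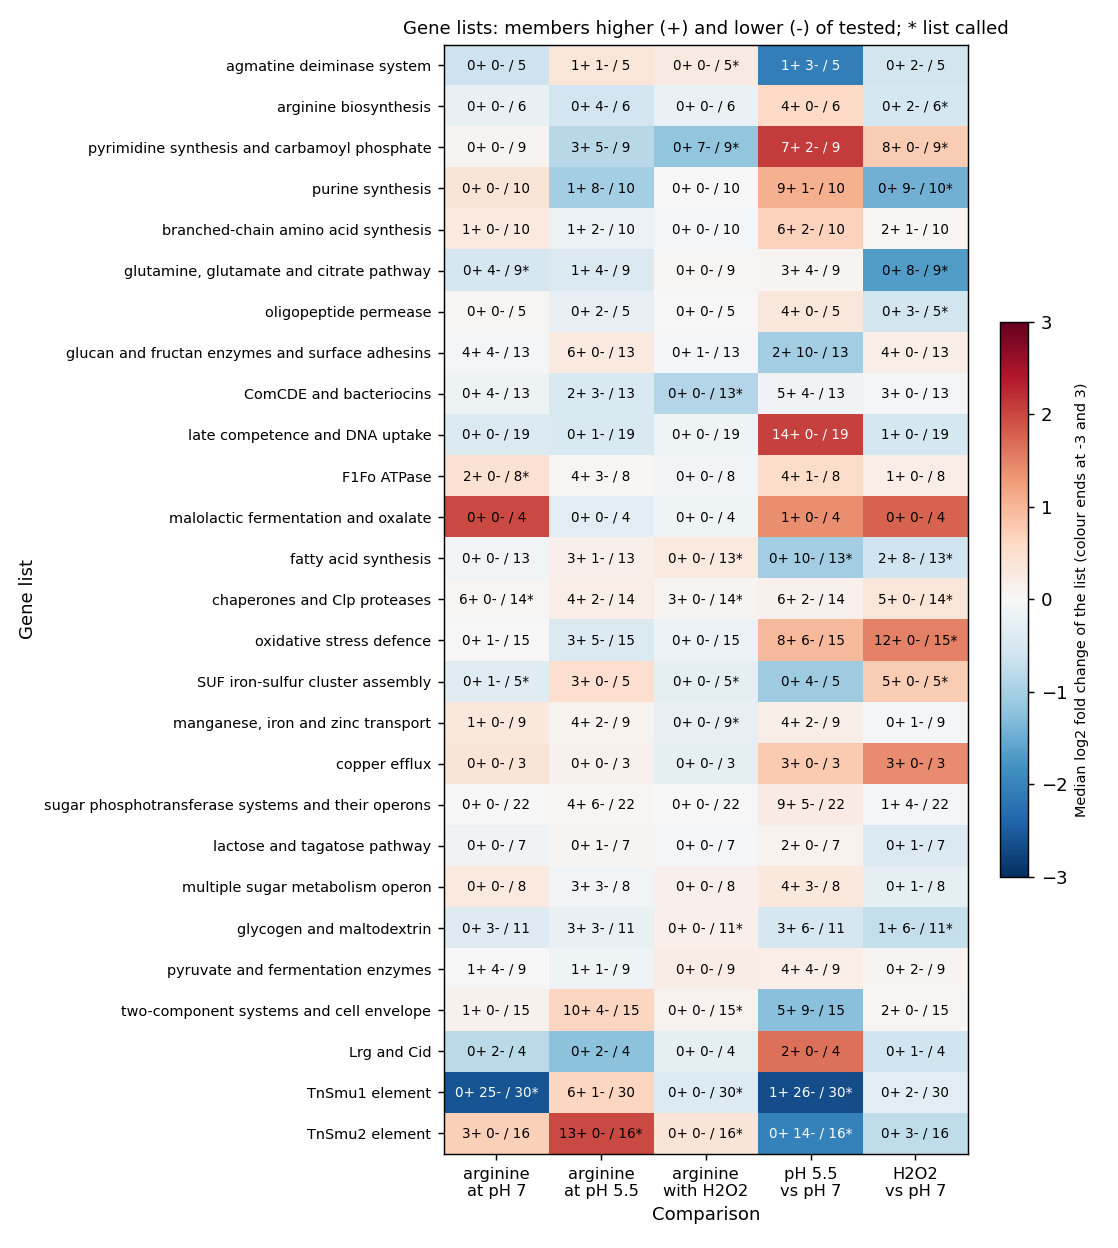
Median log2 fold change of each gene list (rows, colour) in the 5 comparisons of 2 groups (columns), with the number of members called higher (+) and lower (-) of those tested. An asterisk marks a list called by camera at the preset correlation, such as TnSmu1 at pH 7 with arginine, with 25 of 30 members lower.

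With arginine at pH 5.5, the TnSmu2 element rose, with 13 of 16 members higher and a median log2 fold change of 1.98 (camera adjusted p = 0.00277; adjusted p = 0.948 with an estimated correlation). SMU_1339 went from 208 ± 60.4 to 949.2 ± 611.2 CPM (log2 2.20 ± 0.47 SE, edgeR adjusted p = 0.00157, n = 3 each). No other list was called. Of purine synthesis 8 of 10 members fell and 1 rose, with a median of -1.02 (camera adjusted p = 0.0641), and SMU_32 went from 719.5 ± 171.7 to 312.6 ± 134.8 CPM (log2 -1.21, n = 3 each). Adjusted over the list alone 9 fell, and fry, which asks about direction alone, gave adjusted p = 0.0384 for purine and 0.0128 for arginine biosynthesis. The purine list was called by camera in the fit on these 2 groups (adjusted p = 0.0293), without FMC_arginine_pH5.5 replicate 2 (adjusted p = 0.0147), without FMC_pH5.5 replicate 1 or 2 (adjusted p = 0.0411 and 0.0321) and with upper-quartile scaling (adjusted p = 0.0186). Of arginine biosynthesis 4 of 6 fell, SMU_663 (log2 -1.25), SMU_666 (log2 -1.49), SMU_335 and SMU_334. None of the 4 was called in the edgeR fit on these 2 groups alone (adjusted p = 0.0591, 0.0631, 0.0873 and 0.203), where the log2 fold changes of SMU_663 and SMU_666 were -1.19 and -1.42, and SMU_334 was also lost without FMC_pH5.5 replicate 3 (adjusted p = 0.121). Late competence had 1 of 19 lower, a call that ended without FMC_pH5.5 replicate 1 or 3 or FMC_arginine_pH5.5 replicate 1 or 3, and 17 without FMC_arginine_pH5.5 replicate 2. The list was called without FMC_pH5.5 replicate 1 (adjusted p = 0.0365). Both members of the Lrg and Cid list that passed the test fell, SMU_1700c by 1.30 and SMU_1701c by 1.52 on the log2 scale.

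Glucan and fructan enzymes with adhesins had 6 of 13 members higher and none lower, including SMU_910 (log2 1.202 ± 0.196 SE, edgeR adjusted p = 0.000493) and SMU_2028 (log2 1.16). SMU_910 stood at 1084 ± 154 CPM without and 2493 ± 733 CPM with arginine (SD, n = 3 each). Two-component systems and cell envelope had 10 higher and 4 lower of 15, and SUF assembly had 3 of 5 higher. Of all 1933 loci tested 55.5% were called in this comparison, so a list with about that share of members called, or less, does not stand out. Pyrimidine synthesis had 3 higher and 5 lower of 9, oxidative stress defence 3 higher and 5 lower of 15, F1Fo ATPase 4 higher and 3 lower of 8, and metal transport 4 higher and 2 lower of 9. Of the sugar lists, the phosphotransferase systems had 4 higher and 6 lower of 22, the multiple sugar operon 3 and 3 of 8, glycogen and maltodextrin 3 and 3 of 11, and lactose and tagatose 1 lower of 7. Adjusted over the list alone, pyrimidine synthesis had 6 lower, glycogen and maltodextrin 4, and lactose and tagatose 0. The oligopeptide permease had 2 of 5 lower, and chaperones had 4 higher and 2 lower of 14.

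These member counts at pH 5.5 moved with single libraries. Without FMC_pH5.5 replicate 1 or FMC_arginine_pH5.5 replicate 3 the F1Fo ATPase had 2 higher and 2 lower, and chaperones had 2 higher and 1 lower. Without FMC_pH5.5 replicate 1 oxidative stress defence had 3 higher and 2 lower, and without FMC_arginine_pH5.5 replicate 1 the phosphotransferase systems had 3 and 3. The lactose and tagatose call ended without FMC_pH5.5 replicate 1 or 3 or FMC_arginine_pH5.5 replicate 1. In the fit on these 2 groups alone TnSmu2 had 8 members higher, TnSmu1 4 higher and 1 lower, purine synthesis 1 higher and 1 lower, glucan enzymes and adhesins 2 higher, and Lrg and Cid 2 lower. ComCDE and bacteriocins, the F1Fo ATPase, fatty acid synthesis, chaperones, oxidative stress defence, SUF assembly, phosphotransferase systems and two-component systems had 1 higher each, and glycogen and maltodextrin 1 lower. Of the agmatine system, arginine biosynthesis, pyrimidine synthesis, branched-chain amino acid synthesis, the glutamine pathway, oligopeptide permease, late competence, metal transport, lactose and tagatose, multiple sugar metabolism and pyruvate enzymes, edgeR called 0 of 96 members in that fit. Of these 96, 23 had unadjusted p < 0.05 in it, while in the fit on all libraries edgeR called 40 and DESeq2 43.

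In total 1073 loci were called, 565 higher and 508 lower, with 304 and 192 changed at least 2-fold. This count rested on the shared estimate of spread. A fit on these 2 groups alone called 212, and 1012 when FMC_arginine_pH5.5 replicate 2 was also left out. With upper-quartile scaling 67.68% of calls were higher, against 52.66% with TMM, and the median of all loci stood at 0.27.

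With hydrogen peroxide, arginine lowered the pyrimidine synthesis and carbamoyl phosphate list, with 7 of 9 members lower, 8 when adjusted over the list alone, and a median of -1.18 (camera adjusted p = 1.77e-27). This call held with an estimated correlation (adjusted p = 9.58e-05). Of the 7 members called, SMU_858, SMU_859 and SMU_860 kept their calls whichever of the 6 libraries was left out, and SMU_856, SMU_857, SMU_1223 and SMU_1224 lost their calls each time (edgeR adjusted p from 0.0536 to 0.184), with log2 fold changes from -1.39 to -1.10. SMU_858 went from 247.9 ± 25.87 to 97.7 ± 8.73 CPM (log2 -1.34 ± 0.14 SE, edgeR adjusted p = 8.09e-05, n = 3 each), and SMU_859 and SMU_860 had log2 fold changes of -1.27 and -1.14. The ComCDE and bacteriocin list was lower as well, with a median of -0.88 (camera adjusted p = 8.91e-09; adjusted p = 0.0362 with an estimated correlation). None of its 13 members passed over all loci by edgeR, where 9 had an unadjusted p under 0.05 and DESeq2 called 4, and 8 were lower when adjusted over the list alone. Chaperones had 3 of 14 members higher, SMU_80, SMU_81 and SMU_82, with log2 fold changes of 1.10, 1.14 and 0.93, but all 3 lost their calls when any library of these 2 groups except FMC_arginine_H2O2 replicate 2 was left out. Without FMC_H2O2 replicate 1, 2 or 3 the edgeR adjusted p of SMU_82 was 0.0895, 0.155 and 0.113, and without FMC_arginine_H2O2 replicate 1 or 3 it was 0.202 and 0.136.

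The chaperone list was higher (camera adjusted p = 0.0127; adjusted p = 0.229 with an estimated correlation). By edgeR no member passed over all loci in 24 lists with 256 tested members, of which 25 had an unadjusted p under 0.05 and DESeq2 called 6. Called higher among these were the agmatine deiminase system (adjusted p = 0.0154; adjusted p = 0.126 with an estimated correlation), fatty acid synthesis (adjusted p = 9.58e-07; adjusted p = 0.0664 with an estimated correlation), glycogen and maltodextrin (adjusted p = 0.0154; adjusted p = 0.12 with an estimated correlation), two-component systems (adjusted p = 0.0403; adjusted p = 0.406 with an estimated correlation) and TnSmu2 (adjusted p = 0.0181; adjusted p = 0.652 with an estimated correlation). Called lower in the same way were SUF assembly (adjusted p = 0.00487; adjusted p = 0.13 with an estimated correlation), metal transport (adjusted p = 0.0106; adjusted p = 0.12 with an estimated correlation) and TnSmu1 (adjusted p = 5.33e-05; adjusted p = 0.411 with an estimated correlation). Some of these calls ended when 1 library was left out. Without FMC_arginine_H2O2 replicate 3 the agmatine, chaperone, glycogen, metal transport and TnSmu2 lists were not called (adjusted p = 0.0862, 0.0534, 0.0534, 0.11 and 0.342), and without FMC_H2O2 replicate 3 the metal transport, two-component and TnSmu2 lists were not (adjusted p = 0.0618, 0.0556 and 0.17). The two-component list was also lost without FMC_H2O2 replicate 2 or FMC_arginine_H2O2 replicate 2 (adjusted p = 0.0922 and 0.201), TnSmu2 without FMC_arginine_H2O2 replicate 2 (adjusted p = 0.166), and the agmatine list without FMC_H2O2 replicate 1 (adjusted p = 0.0567). In the fit on these 2 groups and on 12 libraries the chaperone list had adjusted p = 0.133 and 0.0524, the agmatine list 0.0506 and 0.0645, and TnSmu2 0.129 and 0.155. With at least 50 counts required in every group mean TnSmu1 was not called (adjusted p = 0.0657), nor was the two-component list with upper-quartile scaling (adjusted p = 0.0544) or TnSmu2 without the loci near 0 at pH 5.5 (adjusted p = 0.223).

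The fit on these 2 groups alone called 7 pyrimidine members lower and 3 chaperone members higher, and 1 metal transport member lower and 1 glycogen member higher. Glucan enzymes and adhesins had 1 member lower with all libraries, a call that ended whichever of the 6 libraries was left out, and 3 lower in that fit. Some lists were called by camera only with 1 library left out. Without FMC_H2O2 replicate 2, arginine biosynthesis and glucan enzymes were lower and pyruvate enzymes higher (adjusted p = 0.0262, 0.0311 and 0.0257), and oxidative stress defence was lower without replicate 3 (adjusted p = 0.00393). Arginine biosynthesis and glucan enzymes were lower without FMC_arginine_H2O2 replicate 1 (adjusted p = 0.0132 and 0.0365), and oxidative stress defence was lower without its replicate 3 (adjusted p = 0.00689). Without FMC_arginine_H2O2 replicate 2, arginine biosynthesis was lower, and the glutamine, multiple sugar and pyruvate lists were higher (adjusted p = 0.0429, 0.0413, 0.0473 and 0.0301).

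In all 22 loci were called by edgeR, 3 higher and 19 lower, and 2 and 14 of these changed at least 2-fold. The count was 65 in a fit on the 12 libraries outside pH 5.5. It was 4, 10 and 6 without FMC_H2O2 replicate 1, 2 or 3, and 3, 11 and 5 without FMC_arginine_H2O2 replicate 1, 2 or 3.

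**Figure D3:**
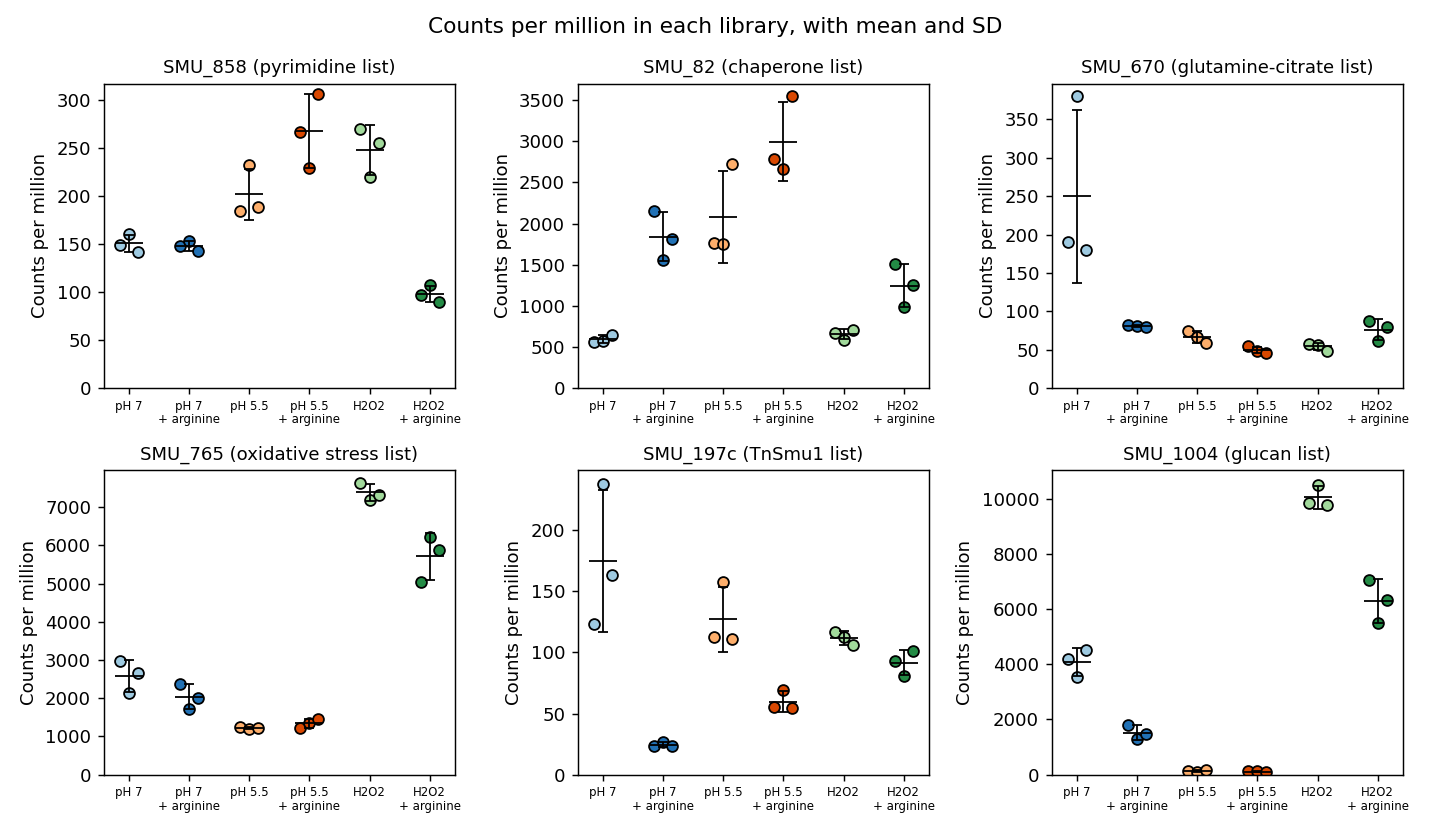
CPM (vertical axes, from 0) of 6 listed loci in each library (points) by group, with the mean and SD (black, n = 3). SMU_858 falls from 247.9 to 97.7 CPM with arginine under hydrogen peroxide, while SMU_82 rises from 590 to 1842 CPM with arginine at pH 7.

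The effects of low pH and of hydrogen peroxide without arginine give the background against which arginine acted. The labels give no pH for the libraries with hydrogen peroxide, so a difference in pH from FMC_pH7 cannot be told apart from an effect of hydrogen peroxide. Of all 1933 loci tested 79.9% were called at pH 5.5, so a list with about that share of members called, or less, does not stand out there. At pH 5.5 the chaperone list had 6 members higher and 2 lower of 14 and was not called (camera adjusted p = 0.326). Its member SMU_83 went from 300.2 ± 22.5 to 5341 ± 1150 CPM (log2 4.15 ± 0.31 SE, edgeR adjusted p = 2.27e-08, n = 3 each). Pyrimidine synthesis had 7 higher and 2 lower of 9, purine synthesis 9 higher and 1 lower of 10, and late competence 14 of 19 higher, which came to 6 without FMC_pH5.5 replicate 3, and the late competence list was called without FMC_pH5.5 replicate 1 (camera adjusted p = 0.0257). SMU_148 of the fermentation list rose by 3.75 and SMU_770c of the metal transport list rose by 4.10 on the log2 scale. Malolactic fermentation had 1 of 4 higher, SMU_135 (log2 1.67), and all 4 in the fit on these 2 groups, and copper efflux had 3 of 3 higher. Glucan enzymes and adhesins had 10 lower and 2 higher of 13, among them SMU_1396 (log2 -3.05) and SMU_610 (log2 -2.10). Fatty acid synthesis was lower, 10 of 13 with SMU_1740 at a log2 fold change of -1.98 (camera adjusted p = 0.0143; adjusted p = 0.681 with an estimated correlation).

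TnSmu1 was lower at pH 5.5, with 26 of 30 members, 27 adjusted over the list alone (camera adjusted p = 0.000344; adjusted p = 0.681 with an estimated correlation), and so was TnSmu2, with 14 of 16 and a median of -2.02 (camera adjusted p = 0.00888; adjusted p = 0.681 with an estimated correlation). Of TnSmu2, 2 members, SMU_1347c and SMU_1348c, were at 0 in all FMC_pH5.5 libraries, so their levels were at least 713-fold and 282-fold lower, from a floor of 3 counts over the group on the TMM scale. With both at that bound the median remained -2.02. Without them it was -1.75, and the list was not called without the 11 loci near 0 at pH 5.5 (adjusted p = 0.0559). With at least 50 counts required in every group mean, neither element was called (adjusted p = 0.442 for TnSmu1 and 0.139 for TnSmu2). A total of 1544 loci were called, 746 higher and 798 lower, and 37.54% of calls were higher with upper-quartile scaling, where the median of all loci was -0.52, against 48.32% with TMM. Neither the counts nor the folds of this comparison can be separated from the different processing of the pH 5.5 files, and the level of SMU_1004, at 127.2 ± 41.15 CPM in FMC_pH5.5 (SD, n = 3), shares the uncertainty given above.

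With hydrogen peroxide, oxidative stress defence rose with 12 of 15 members higher and a median of 1.51 (camera adjusted p = 2.9e-07; adjusted p = 0.132 with an estimated correlation). SMU_765 went from 2587 ± 424.5 to 7391 ± 227.3 CPM (log2 1.51 ± 0.15 SE, edgeR adjusted p = 1.7e-06, n = 3 each) and SMU_1869 rose by 2.40 on the log2 scale. SUF assembly rose in 5 of 5 members (camera adjusted p = 0.00103; adjusted p = 0.132 with an estimated correlation), pyrimidine synthesis in 8 of 9 (camera adjusted p = 0.0004; adjusted p = 0.132 with an estimated correlation), and copper efflux in 3 of 3. The pyrimidine members called came to 5 without FMC_pH7 replicate 1 or 2 or FMC_H2O2 replicate 1 or 3. Chaperones had 5 of 14 higher, 3 without FMC_pH7 replicate 1 or 2 or FMC_H2O2 replicate 1 or 2, and 11 in the fit on these 2 groups, led by SMU_1955 at a log2 fold change of 1.41 (camera adjusted p = 0.00321; adjusted p = 0.164 with an estimated correlation). Purine synthesis fell in 9 of 10 members, with SMU_35 at a log2 fold change of -1.57 (camera adjusted p = 1.92e-06; adjusted p = 0.164 with an estimated correlation), and the glutamine, glutamate and citrate pathway fell in 8 of 9, with SMU_364 at 2277 ± 389 and 716 ± 34.2 CPM (n = 3 each; camera adjusted p = 1.99e-07; adjusted p = 0.132 with an estimated correlation).

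Also lower were arginine biosynthesis with 2 of 6 (camera adjusted p = 0.0077; adjusted p = 0.164 with an estimated correlation), oligopeptide permease with 3 of 5, 1 without FMC_H2O2 replicate 2 and 4 adjusted over the list alone (adjusted p = 0.0155; adjusted p = 0.328 with an estimated correlation), fatty acid synthesis with 8 lower and 2 higher of 13 (adjusted p = 0.00156; adjusted p = 0.164 with an estimated correlation) and glycogen and maltodextrin with 6 lower and 1 higher of 11 (adjusted p = 0.0463; adjusted p = 0.164 with an estimated correlation). The last was not called in the fits on these 2 groups or on 12 libraries (adjusted p = 0.191 and 0.147), with upper-quartile scaling (adjusted p = 0.0508), or without FMC_pH7 replicate 2 or FMC_H2O2 replicate 3 (adjusted p = 0.0507 and 0.0608). The fit on these 2 groups called more members in many lists. Glycogen and maltodextrin had 5 higher and 6 lower there, arginine biosynthesis 3 lower, and oligopeptide permease 4 lower. TnSmu2 had 3 lower with all libraries and 9 lower and 1 higher in that fit, and the phosphotransferase systems went from 1 higher and 4 lower to 4 and 6. Two-component systems went from 2 higher to 6 higher and 4 lower, branched-chain synthesis from 2 higher and 1 lower to 4 and 3, and glucan enzymes from 4 higher to 6 higher and 1 lower. Late competence went from 1 higher to 1 higher and 5 lower, the F1Fo ATPase from 1 to 4 higher, multiple sugar metabolism from 1 to 4 lower, and ComCDE from 3 higher to 3 higher and 2 lower. Metal transport went from 1 lower to 2 higher and 1 lower, pyruvate enzymes from 2 lower to 3 higher and 1 lower, and malolactic fermentation had 1 lower in that fit. The agmatine system and TnSmu1 went from 2 lower to 1 lower each. Camera called TnSmu2 lower in that fit (adjusted p = 0.0384) and without FMC_pH7 replicate 3 or FMC_H2O2 replicate 1 (adjusted p = 0.0471 and 0.0324), TnSmu1 lower without FMC_pH7 replicate 3 (adjusted p = 0.00347), and glucan enzymes higher without FMC_pH7 replicate 3 or FMC_H2O2 replicate 2 (adjusted p = 0.0471 and 0.0332). Outside the lists SMU_932 and SMU_936 rose by 6.24 and 5.95 on the log2 scale, and SMU_1521 and SMU_1520 had log2 fold changes of -2.52 and -2.44. Of the 1933 loci tested 23.95% were called, 272 of them higher, which was 58.75% of the calls. The count was 1039 in a fit on these 2 groups and 1020 in a fit on 12 libraries, and 45.61% of calls were higher with upper-quartile scaling. The rRNA share of FMC_H2O2 was also lower than that of FMC_pH7, as given above.

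Differences between the arginine effects were tested directly. Between pH 5.5 and pH 7 the effect differed for 940 of 1933 loci (48.6%), lower at pH 5.5 for 441 and higher for the rest. TnSmu1 had 29 of 30 members higher (camera adjusted p = 3.6e-12; adjusted p = 0.888 with an estimated correlation), and purine synthesis had 8 lower and 1 higher of 10 (camera adjusted p = 0.0198; adjusted p = 0.888 with an estimated correlation), a call lost without FMC_pH5.5 replicate 3 (adjusted p = 0.0544). Most TnSmu1 members were already lower at pH 5.5 without arginine, as given above. How far their low level there limited a further fall, and so set this difference, was not tested. SUF assembly had 4 of 5 higher, and the list was called with at least 50 counts required and without FMC_arginine_pH7 replicate 1, FMC_pH5.5 replicate 3 or FMC_arginine_pH5.5 replicate 1 (adjusted p = 0.0179, 0.0495, 0.047 and 0.0288). A fit on these 4 groups alone called 623 loci, and with upper-quartile scaling, where the median of all loci was 0.36, 70.94% of calls were higher against 53.09% with TMM. Between hydrogen peroxide and pH 7 the effect differed for 92 loci, 38 higher and 54 lower. Pyrimidine synthesis had 5 of 9 members lower (camera adjusted p = 6.63e-10), which held with an estimated correlation (adjusted p = 0.0141), and 8 members were lower when adjusted over the list alone. The 5 came to 3 without FMC_pH7 replicate 1 or FMC_arginine_H2O2 replicate 3. TnSmu1 had 19 of 30 higher, and 23 adjusted over the list alone (camera adjusted p = 3.82e-20; adjusted p = 0.144 with an estimated correlation). Its 19 came to 11 without FMC_pH7 replicate 2 and to 10 without FMC_arginine_pH7 replicate 1, FMC_H2O2 replicate 3 or FMC_arginine_H2O2 replicate 3. Of the others, the glutamine, fatty acid, agmatine and glycogen lists were higher (adjusted p = 0.000322, 0.00631, 0.0183 and 0.0186), which gave adjusted p = 0.181, 0.23, 0.145 and 0.145 with an estimated correlation. The F1Fo ATPase and metal transport lists were lower (adjusted p = 0.00649 and 0.00766), which gave adjusted p = 0.181 and 0.145 with an estimated correlation, and the agmatine list was lost without FMC_pH7 replicate 3 (adjusted p = 0.0862) and in the fit on these 4 groups (adjusted p = 0.0601).

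For this difference the count was 386 in a fit on the 4 groups of the contrast. That fit called all 9 pyrimidine members lower, 21 TnSmu1 members higher, 5 F1Fo ATPase and 3 metal transport members lower, and 6 fatty acid, 4 glutamine, 4 glycogen and 1 agmatine members higher. Camera called TnSmu2 lower without FMC_arginine_pH7 replicate 1 and pyruvate enzymes higher without FMC_pH7 replicate 1 (adjusted p = 0.0198 and 0.0361). It was 60 without FMC_pH7 replicate 1 or replicate 2, 58 without FMC_arginine_pH7 replicate 1 or replicate 3, and 49 without FMC_H2O2 replicate 3 or FMC_arginine_H2O2 replicate 3.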

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

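The tests of label exchange, depth, a wrong label, shared reads and the pH axis below were chosen after the patterns were seen; the counts of splits were planned before.

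The arginine effect differed between conditions by a test of the difference itself. Between pH 5.5 and pH 7, 940 loci differed, the most at SMU_1772c (log2 difference 4.80), SMU_46 (4.66), SMU_205c (4.54), SMU_1576c (4.23) and SMU_605 (4.21) on the higher side, and at SMU_694c (-3.52), SMU_936 (-3.38), SMU_1067c (-3.19), SMU_934 (-3.16) and SMU_961 (-2.97) on the lower side. Between hydrogen peroxide and pH 7, 92 loci differed, the most at SMU_206c (3.18), SMU_205c (2.76), SMU_197c (2.55), SMU_198c (2.54) and SMU_201c (2.44), and at SMU_1928 (-3.11), SMU_936 (-3.03), SMU_933 (-3.02), SMU_934 (-2.98) and SMU_1927 (-2.91). Of 100 splits drawn for the pH difference, 1, the real one, gave as many loci (highest other 740), and for the hydrogen peroxide difference 3 of 100 did (highest other 122). These splits exchange arginine labels within each condition, so at the 0.05 level chance can be excluded only in the sense of no arginine effect in either condition. They do not test whether the effects were equal, since the highest other split kept the real labels at pH 5.5 in the first case and at pH 7 in the second.

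For the comparisons of 2 groups there are only 10 splits of the 6 libraries, too few for a share under 0.05. In each, 1 split, the real one, gave the highest count. The real counts were 194, 22 and 1544 for arginine at pH 7, arginine with hydrogen peroxide and pH 5.5, and 23.95% of 1933 loci for hydrogen peroxide, against 0 in the highest other split of each. For arginine at pH 5.5 the real count was 1073 and the highest other was 885, from the split that exchanged FMC_arginine_pH5.5 replicate 2 with FMC_pH5.5 replicate 2, which points to a structure of those samples.

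Counts of tRNA rows, outside the main measurement, exceeded the level of FMC_pH7, with no overlap between the libraries. As a share of tRNA and mRNA counts they averaged 0.445% in FMC_arginine_pH7, 0.321% in FMC_H2O2 and 0.324% in FMC_arginine_H2O2, against 0.268% in FMC_pH7 (n = 3 each). The same 3 groups held less rRNA, 43.2%, 46.1% and 45.4% of counts against 69.5%, and the 2 differences were not separated. With 3 libraries against 3, 10% of such comparisons show no overlap by chance.

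FMC_arginine_pH5.5 replicate 2 lay near the libraries without arginine. Its correlation across loci was 0.968, 0.982 and 0.982 with the FMC_pH5.5 libraries and 0.935 and 0.963 with its own group, so the lowest of the former exceeded the highest of the latter by 0.005. An exchange of labels between the 2 groups needs an FMC_pH5.5 library out of place, and 0 of 3 correlated better with FMC_arginine_pH5.5 replicates 1 and 3 than with its own group. Lower depth is argued against as well, since replicates 1 and 3 thinned to its total stayed at 0.597 and 0.408 on the axis, against 0.147. A single wrong label and a weaker response of that sample cannot be told apart, because both place it near the libraries without arginine.

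At pH 5.5, 11 loci were near 0, chosen as under 2 CPM in each of the 6 libraries and over 10 CPM in each of the 12 others, before scaling. They had totals of 0 to 23 counts over the 6 libraries and at least 44 counts in each of the 12 other libraries. The lowest count expected in a pH 5.5 library was 44.5, so lower depth alone would not bring them near 0. The rule that chose them fixed this outcome in advance, so it is no separate test of depth. If reads that map to several places were left out of the pH 5.5 counts alone, these loci may be copies of others, and 10 of the 11 had a partner among all loci within 1.25-fold in at least 11 of the 12 libraries. That count did not exceed the 95th percentile of random loci (10), the bound set for counting against this explanation, but the bound was a poor one, since random loci reached a median of 7 and a highest value of 11, so the test was read as deciding nothing. A further test, added after that outcome, found 6 with a partner within the set, against a median of 0 and a 95th percentile of 2 in 10000 random sets, of which 5 reached 6, which is consistent with left-out shared reads for those loci. An effect of pH stays open, since processing and pH cannot be told apart.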

How the results depend on the processing

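Alternatives chosen after seeing the data were the distinct count columns, leaving out loci near 0 at pH 5.5, the 12 libraries outside pH 5.5, and leaving out FMC_arginine_pH5.5 replicate 2 from the fit on its 2 groups. Under DESeq2 as scaling or test, upper-quartile scaling, limma-voom, the other filters, the distinct columns and the loci near 0 left out, the 7 counts of changed loci stayed within 1.5 times. Values here are the percentage of tested loci called. With all libraries it was 10.04% for arginine at pH 7, 55.5% for arginine at pH 5.5, 1.14% for arginine with hydrogen peroxide, 79.9% for pH 5.5, 24.0% for hydrogen peroxide, 48.6% for the difference between pH 5.5 and pH 7 and 4.76% for the difference between hydrogen peroxide and pH 7. Fits on the groups of the contrast alone gave 26.1% for arginine at pH 7, 11.6% for arginine at pH 5.5, 54.2% for hydrogen peroxide, 32.5% for the difference at pH 5.5 and 20% for that with hydrogen peroxide, while arginine with hydrogen peroxide and pH 5.5 stayed within 1.5 times. The 12 libraries outside pH 5.5 gave 32.3%, 3.37%, 52.9% and 20% for arginine at pH 7, arginine with hydrogen peroxide, hydrogen peroxide and the latter difference. A fit on the 2 groups at pH 5.5 without FMC_arginine_pH5.5 replicate 2 called 1012 loci. These fits hold fewer libraries and estimate spread only from the groups they keep, while the fit on all libraries estimates it over all 6 groups. The variation within groups was 24.9% and 37.4% at pH 5.5 and at most 17.3% in the 4 other groups. The estimate over all 6 groups, 22.2%, was thus lower than in the pH 5.5 groups and higher than in the others. Of 30 list calls in the comparisons of 2 groups 2 held with an estimated correlation, and of 10 in the differences 1 held. Small changes were often missed at these depths, since in simulations of arginine at pH 7 changes of 0.5 on the log2 scale were recovered in 16.3% of loci.

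Replicate numbers do not pair the libraries. Of 15 pairs of groups and numbers 3 had correlated deviations over 0.1, the range was -0.738 to 0.268, and in 5 pairs the library correlated best with its own number. With the replicate number as a block arginine with hydrogen peroxide gave 12 loci (0.621%) against 22, and the other 6 counts stayed within 1.5 times.

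With 1 library left out, the percentage called ranged from 6.31% to 7.07% for arginine at pH 7, from 43.1% to 67.7% for arginine at pH 5.5, from 0.155% to 0.569% for arginine with hydrogen peroxide, from 76.7% to 79.9% for pH 5.5, from 16.5% to 19.2% for hydrogen peroxide, from 36.9% to 63.0% for the difference at pH 5.5 and from 2.53% to 4.45% for that with hydrogen peroxide. Among 477 results of single loci, other settings left 4796 of 5001 values with the same direction and call, and leaving out a library left 2654 of 2982.

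Changes of sign follow as log2 fold changes, and the cause was not tested. For arginine with hydrogen peroxide, SMU_256 and SMU_286 came to 0.010 and 0.010 with DESeq2 scaling, 0.004 and 0.002 with upper-quartile scaling, and 0.009 and 0.009 in the DESeq2 test. In limma-voom SMU_286 came to 0.006, SMU_137 to 0.376 and SMU_221c to -0.015, and SMU_137 came to 0.757 with the replicate block. For arginine at pH 7, SMU_1739 came to -0.036 with upper-quartile scaling and -0.003 with at least 50 counts required. For pH 5.5, upper-quartile scaling gave -0.015 for SMU_335, -0.097 for SMU_259 and -0.097 for SMU_255, all 3 called with TMM.

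With 1 library left out, the ranges that crossed 0 were as follows. For arginine at pH 7 they were -0.198 to 0.078 for SMU_1491, -0.247 to 0.067 for SMU_1490, -0.017 to 0.156 for SMU_255 and -0.394 to 2.701 for SMU_137. For hydrogen peroxide they were -3.164 to 0.207 for SMU_1421 and -0.785 to 2.668 for SMU_137, and for arginine at pH 5.5 -0.058 to 0.228 for SMU_135. For arginine with hydrogen peroxide they were -0.128 to 0.117 for SMU_286, -0.113 to 0.058 for SMU_135, -0.010 to 0.634 for SMU_262, -0.080 to 0.101 for SMU_365, -0.110 to 0.147 for SMU_287, -2.688 to 2.742 for SMU_137, -0.117 to 0.056 for SMU_1490, -0.292 to 0.041 for SMU_48, -0.090 to 0.020 for SMU_2128, -0.079 to 0.088 for SMU_256, -0.161 to 0.009 for SMU_1528, -0.174 to 0.221 for SMU_221c and -0.067 to 0.273 for SMU_220c. Of these results SMU_1421 alone was called with all libraries, and it came to 0.207 without FMC_pH7 replicate 3.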

Other observations

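The pattern on the pH axis and the tests of it, the splits of shared libraries and the loci SMU_932 to SMU_936 were chosen after the data were seen.

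SMU_932, SMU_933, SMU_934, SMU_935 and SMU_936 were each called higher with hydrogen peroxide, with log2 fold changes of 5.78 to 6.24, and with arginine at pH 7, with 2.34 to 2.58. They were picked from the highest fold changes, belong to no list and were not tested as a group. SMU_936 stood at 47.0 ± 4.94 CPM in FMC_pH7, 282 ± 42.6 in FMC_arginine_pH7, 2911 ± 611 in FMC_H2O2 and 2133 ± 536 in FMC_arginine_H2O2 (SD, n = 3 each). With hydrogen peroxide present, arginine gave a log2 fold change of -0.45 for it (edgeR adjusted p = 0.876). Across loci, which are not independent replicates, the fold changes of hydrogen peroxide and of arginine at pH 7 had a Pearson correlation of 0.463 and a Spearman correlation of 0.456. Both are measured against the FMC_pH7 libraries, and unchanged groups simulated against those libraries gave a mean correlation of 0.507. The covariance was 0.202, against 0.0395 in the simulations, a difference of 0.162. Of 272 loci higher with hydrogen peroxide, 48 were also higher with arginine, where independent lists would share 12.8, and 30 were lower in both, where independent lists would share 10.2. These lists are not independent, since both use the FMC_pH7 libraries, and the overlap without an effect was not simulated. With different FMC_pH7 libraries in the 2 comparisons the Pearson correlation was 0.317 to 0.436 over 6 splits, while differences between libraries of 1 group correlated with those of another group by up to 0.643 in absolute value. In the fit on 12 libraries the counts behind the overlaps were 1020 and 623.

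Arginine at pH 5.5 moved loci toward their pH 7 level. Across loci the fold changes of arginine at pH 5.5 and of pH 5.5 against pH 7 had a correlation of -0.824 (Spearman -0.855), but both use the FMC_pH5.5 libraries, and unchanged groups simulated against those libraries gave a mean correlation of -0.534. Noise of these libraries is argued against as the whole cause, because with different FMC_pH5.5 libraries in the 2 comparisons the correlation was -0.809 to -0.708 over 6 splits, beyond the 0.411 that differences within groups reached, and the covariance was -1.43 against -0.0526 to -0.0406 in 100 simulations without effects. With the 6 libraries thinned to 2472796 counts each the correlation was -0.822, which decides nothing on depth, since the bound set for it was closer to 0 than the value that shared libraries alone gave. A candidate explanation, not tested here because no culture pH is given, is that arginine raised the pH of the medium; carry-over between samples was not tested either, and FMC_arginine_pH5.5 replicate 2 showed little of the shift.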
